A study of Mus musculus with 12 samples.

How the data were processed

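Per the labels, Cy3-labelled cRNA was made from total RNA and hybridised to single-colour Agilent mouse arrays of design 028005, 8 arrays to a slide, with 60 nt probes placed on mm9. Per the file headers, the spot intensity values were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted the background and detrended the processed signal of each array, with no step between arrays. Per the submitters' processing notes the software was Agilent Feature Extraction 9.1 and limma, with no version given for limma. The deposited series table holds log2 intensities that the authors put on a common distribution across the 12 arrays, as its column medians (6.181 to 6.225) and quartiles (equal to within 0.058) show. Its 12 columns correlated at 0.9888 to 0.9939 with the log2 processed signal of the same array, which was the best match of the 12 arrays for each column. With the log2 median signal minus the median background they correlated at 0.9984 to 0.9998 on slides 1 and 2 but at 0.9907 to 0.9922 on slide 3. How the authors treated background is not stated, and why slide 3 differs is not known. The table served only as an alternative.

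Values were the log2 processed signal minus the 75th percentile of the non-control spots of the array, after spots marked as non-uniform or population outliers were dropped, averaged over the spots of a probe. Each array held 59305 non-control and 3671 control spots, 0 spots were saturated, and the 75th percentile ran from 629.38 (E15 cortex) to 1129.72 (CHIR_11-16 replicate 1). A probe passed when it was well above background on both arrays of at least 1 culture group and kept an unmarked spot on each of the 8 culture arrays. Of 55681 non-control probes 36430 passed, 223 being dropped for want of an unmarked spot, and the brightest passing probe of each gene stood for 25538 genes. Probes were named by the transcript accession in the culture files (28026) or the embryo files (41), by a current (1950) or older (362) symbol, or by the name the file gave (25302). Of the probes, 6145 carried another accession in the embryo files than in the culture files. A check for arrays with identical values found 0 pairs.

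Groups of cultures were compared in limma (lmFit and eBayes, robust and trend options off) with 1 mean per group over the 8 culture arrays, and the agonist comparison with 1 mean for the 4 agonist and 1 for the 4 inhibitor cultures. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over 25538 genes, 2-sided, with no fold minimum. Each fit was repeated with slide as a block, since the arrays of replicate 1 lay on slide 2 and those of replicate 2 on slide 3 and both slides held all 4 groups. Deviations of arrays on the same slide from their group means correlated at 0.579 to 0.667 over the 6 pairs of groups, so that replicates with the same number were treated as paired by slide. The median residual SD was 0.317 without and 0.182 with the block, and an F test over the 4 groups called 0 genes without and 14 with it. With slide as a block the lone array of a group left by leave-one-out fits was assumed to vary like those of the other groups, as it was without the block.

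The 21 gene lists were fixed before the data were examined, as were the comparisons, thresholds, first alternatives and the rule for named genes. They cover WNT/beta-catenin targets; WNT ligands, receptors and modulators; BMP targets; cortical hem, roof plate and choroid plexus; hippocampal, isocortical, pallial progenitor, ventral telencephalon and GABAergic, midbrain and isthmus, diencephalon and hypothalamus, and hindbrain and spinal HOX genes. The others cover Cajal-Retzius cells, pan-neuronal and synaptic genes, axon guidance, proliferation, pluripotency, astrocytes and the oligodendrocyte lineage, neural crest and mesenchyme, endoderm, epithelium and muscle, blood, endothelium and microglia, and stress, apoptosis and hypoxia. Lists with at least 5 measured genes were tested by camera (preset correlation 0.01, then an estimated one) and by fry, adjusted over the lists of a comparison. The 6 signatures held genes at least 2-fold higher in 1 embryonic tissue than in each of the other 3, and genes at least 2-fold different between hippocampus and cortex. They were drawn only from the genes tested in the cultures, so embryonic genes that no culture group expressed are missing.

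Named genes were the 8 largest rises and 8 largest falls among called genes with a symbol that is not a predicted or anonymous name, up to 4 called members of each list or signature, and anchor genes in every comparison whatever their result (Axin2, Lef1, Sp5, Wnt8b, Prox1, Zbtb20, Emx2, Bcl11b, Tbr1, Fezf2, En1, Dlx2, Reln, Mki67, and others whose result is not reported here). For the embryonic tissues they were the 5 largest differences each way between hippocampus and cortex. The use of the rule on calls with the slide block was chosen after seeing the data, and so were the tests against WiBi_0-16, the further alternatives with the block, and the list of 20 mesenchymal genes described with the mesenchyme result. Of the named results 19 had over 1 passing probe, and 0 had a probe of opposite sign.

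Alternatives were normexp background correction of the median signal with an offset of 50 and quantile normalization, quantile normalization of the processed signal, median scaling, the deposited table, no filter on dim probes, a filter on all 8 culture arrays, a trended prior, the mean of all passing probes, only the 2 groups compared, a 2-fold minimum, and leaving out each array in turn. The mean signal of spots was not used here. Centred correlations subtracted from each gene its mean over the 8 cultures or the 4 tissues, over genes well above background on an embryo array. Percentiles of list medians in the embryo came from 10000 random lists of the same size and signal level.

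The fit was tested on simulated data with 50 changed genes per size among 25538. For CHIR_8-16 against WiBi_0-11 it recovered 0%, 16% and 52% of genes changed by 1, 2 and 3 log2 units without the block, with 0 false calls, and 18%, 90% and 96% with the block, with 9 false calls. For the agonist comparison it recovered 32%, 84% and 92% without the block (2 false calls) and 78%, 96% and 98% with it (5 false calls). Of 100 simulated lists of 20 genes, camera called 1% when unshifted and 100% when shifted by 0.5 log2 units, at an unadjusted threshold of 0.05. Versions were R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15 and matplotlib 3.10.9.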

Results

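RNA from neurons derived from mouse embryonic stem cells was measured on 8 single-colour Agilent expression arrays, 2 for each of 4 culture groups, at day 16 of differentiation. Per the labels, all 4 groups received the WNT pathway inhibitor 53AH (2.5 µM) and the BMP receptor inhibitor LDN193189 (0.25 µM) from day 0. WiBi_0-11 kept both inhibitors until day 11 and WiBi_0-16 until day 16. In CHIR_8-16 the inhibitors ended at day 8 and the WNT agonist CHIR, a GSK3 inhibitor, was given at 3 µM from day 8 to day 16, although the steps of the growth protocol add up to a change at day 7. In CHIR_11-16 the agonist followed the inhibitors from day 11 to day 16, at a dose that the labels do not state. The labels name WiBi 11 as isocortical and CHIR8 as hippocampal cultures. Another 4 arrays measured cortex, hippocampus, ventral telencephalon and midbrain of E15 mouse embryos, 1 array per tissue, so no spread is known for them. Each sample pooled the RNA of 3 sets of experiments.

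Between 59.06% and 71.18% of the non-control spots of an array were well above background, and 25538 genes were tested in the cultures. The number of arrays, 2 per culture group, limits the precision of every value. The p-values measure only the spread between these samples, which may be technical. Replicate 1 of each culture group lay on slide 2 and replicate 2 on slide 3, and 8778 genes differed between these slides (6208 higher and 2570 lower on slide 3, limma, adjusted p < 0.05). On slide 3 the midbrain and isthmus list was higher by a median log2 of 0.90 (adjusted p = 0.019), the blood, endothelium and microglia list by 0.94 (adjusted p = 0.033) and the E15 ventral telencephalon signature by 0.45 (adjusted p = 0.019). The shift was not particular to these lists. Medians were 1.06 for pluripotency, 1.06 for endoderm, epithelium and muscle and 1.01 for HOX genes, which did not pass. The pallial progenitor and pan-neuronal lists differed by -0.11 each. Both slides held all 4 groups, so each comparison is given without and with slide as a block, and differences within slide 2 and slide 3 stand beside it. Where an array of the lower side of a comparison was not well above background for a gene, its signal was set to at least the lowest signal called well above background there, and the fold is a lower bound ("at least").

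The comparison of CHIR_8-16 with WiBi_0-11 asked how cultures of the hippocampal protocol differed from those of the isocortical protocol. Without a slide term 3 genes passed, all 3 lower in CHIR_8-16 (n = 2 against 2), and 2457 genes had an unadjusted p under 0.05. Egfr, the receptor of epidermal growth factor, was 11.9-fold lower (log2 -3.57, SE 0.22, adjusted p = 0.038; mm9 chr11:16813815-16813874). Frat1, which binds GSK3 and promotes WNT signalling, was 6.88-fold lower (log2 -2.78, SE 0.16, adjusted p = 0.038; chr19:41906864-41906923). Ibsp, a bone matrix sialoprotein, was at least 10.3-fold higher in WiBi_0-11 (adjusted p = 0.038; chr5:104740413-104740472), and by another passing probe for it at least 3.62-fold. Within slide 2 and slide 3 the log2 differences were -3.92 and -3.22 for Egfr and -2.87 and -2.69 for Frat1. Leaving out either array of either group, 4 arrays in all, ended all 3 calls (0 genes called by limma each time), and so did fitting only the 2 groups compared, averaging the probes of a gene, or testing dim probes as well (0 genes each).

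With slide as a block 79 genes passed, 20 higher and 59 lower in CHIR_8-16, and 5635 genes had an unadjusted p under 0.05. Neurog2, a proneural factor of pallial progenitors, rose 8.81-fold (log2 3.14, SE 0.25, adjusted p = 0.024; 2.69 on slide 2 and 3.59 on slide 3; chr3:127337805-127337864). Lef1, a transcription factor that carries WNT signals, rose 7.82-fold (log2 2.97, SE 0.22, adjusted p = 0.024; 2.98 and 2.96; chr3:130926200-130926259). The WNT feedback inhibitor Nkd1 rose 4.12-fold, the forebrain homeobox gene Otx1 at least 4.47-fold, the embryonic myosin gene Myh3 at least 4.63-fold and the cytokine signal transducer Stat4 4.93-fold, with adjusted p from 0.02 to 0.041. Slc35d3 was at least 2.52-fold and AU016765 at least 2.82-fold higher in CHIR_8-16. Olig1 fell 34.1-fold (log2 -5.09, SE 0.47, adjusted p = 0.037) and Olig2 9.97-fold (SE 0.32, adjusted p = 0.039), and Gpr17 was at least 7.83-fold higher in WiBi_0-11, while their list, astrocytes and the oligodendrocyte lineage, did not pass (adjusted p = 0.3, 0.18 with the block; 3 up and 3 down when adjusted over the list alone). Sp8, a factor of interneuron progenitors, fell 14.1-fold (log2 -3.82, SE 0.22, adjusted p = 0.017), though another passing probe for it gave a log2 difference of -0.58. Gad1, the main GABA-synthesising enzyme, fell 6.45-fold (SE 0.28, adjusted p = 0.047), and neuropeptide Npy was at least 26.6-fold higher in WiBi_0-11 (adjusted p = 0.017). The fibrillar collagen Col3a1 fell 6.99-fold, the WNT ligand Wnt7a 3.53-fold and the guanine deaminase Gda 10.5-fold, and the interleukin receptor Il23r was at least 5.06-fold higher in WiBi_0-11. Other passing probes gave log2 differences of 1.24 for Nkd1, 3.42 for Lef1 and, at the smallest, -1.94 for Egfr. Another probe for Myh3 was at least 3.14-fold higher in CHIR_8-16, and that for Gda was not well above background in either group. The blocked count was 0 without WiBi_0-11 replicate 1 and without WiBi_0-11 replicate 2. It was 110 without CHIR_8-16 replicate 1 (62 higher, 48 lower, 34 of them among the 79) and 85 without CHIR_8-16 replicate 2 (48 higher, 37 lower, 20 of them among the 79), so that most of these calls were other genes and most were higher in CHIR_8-16. Genes higher in CHIR_8-16 made up 25.3% of the 79 calls, 56.4% and 56.5% of the calls without these arrays, 40.1% of 1030 calls with a trended prior and 35.6% of 444 calls after normexp background correction and quantile normalization.

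Lef1, which is also in the hippocampal list, passed between CHIR_8-16 and WiBi_0-11 with the block only. The other genes below that mark hippocampus or isocortex, named in each comparison whatever their result, did not pass in either fit. The log2 difference was 0.45 for Prox1 and 0.03 for Zbtb20, both factors of hippocampal neurons, 1.78 for Wnt8b, a WNT ligand of the hippocampal primordium, and 0.27 for the pallial factor Emx2. It was -0.47 for Bcl11b, 0.28 for Tbr1 and 0.60 for Fezf2, which specify cortical projection neurons. The WNT targets Axin2 and Sp5 differed by 1.27 and 3.01, the interneuron factor Dlx2 by -3.39, the Cajal-Retzius gene Reln by 0.25 and the proliferation gene Mki67 by 0.19. Adjusted p of these genes, Lef1 aside, ran from 0.24 for Dlx2 to 1 for Zbtb20 without the block. Wnt8b differed by 0.34 on slide 2 and 3.21 on slide 3. En1 was not measured, since no probe for it passed.

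Of the 21 gene lists, 5 passed between CHIR_8-16 and WiBi_0-11 by camera with a preset correlation of 0.01. The WNT/beta-catenin targets were higher, with a median log2 of 0.63 over 16 measured genes (0.91 on slide 2, 0.68 on slide 3; adjusted p = 0.0024, and 0.055 with slide as a block). Adjusted p = 0.38 with an estimated correlation. In this list 12 members were higher and 4 lower, 5 rose and 1 fell when adjusted over the list alone, and with the block Lef1 and Nkd1 rose and Sp8 fell over all genes. The pallial progenitors were higher by a median of 0.47 over 22 genes (0.58 and 0.51; 17 higher, 5 lower; adjusted p = 0.00016, 0.0026 with the block), 6 of them adjusted over the list alone, and adjusted p = 0.36 with an estimated correlation. The ventral telencephalon and GABAergic list was lower, with a median of -0.94 over 21 genes (-0.52 and -1.87; 5 higher, 16 lower; adjusted p = 3.6e-05, 0.00029 with the block), with 1 member up and 8 down when adjusted over the list alone, and adjusted p = 0.42 with an estimated correlation. The neural crest and mesenchyme list was lower, with a median of -0.85 over 18 genes (-0.82 and -0.97; 6 higher, 12 lower; adjusted p = 0.00028, 0.00094 with the block), with 1 up and 5 down when adjusted over the list alone, and adjusted p = 0.38 with an estimated correlation. The pan-neuronal and synaptic list was lower, with a median of -0.23 over 25 genes (-0.24 and -0.30; 6 higher, 19 lower, 0 adjusted over the list alone; adjusted p = 0.00092, 0.00088 with the block), and adjusted p = 0.38 with an estimated correlation. Adjusted p of the pan-neuronal list was 0.099 without WiBi_0-11 replicate 1 and 0.31 without CHIR_8-16 replicate 2, and 12 lists passed without CHIR_8-16 replicate 1.

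The lists named for the regions that the protocols aim at did not pass between CHIR_8-16 and WiBi_0-11. The hippocampal list had a median log2 of 0.09 (22 genes, 12 higher, 10 lower; adjusted p = 0.86), with 2 up and 2 down when adjusted over the list alone, and the isocortical list -0.01 (28 genes, 14 higher, 14 lower; adjusted p = 0.84), with 0 up and 1 down. Medians of the other lists that did not pass were 0.14 for WNT ligands, receptors and modulators, 0.26 for BMP pathway targets, 0.26 for cortical hem, roof plate and choroid plexus, 0.31 for midbrain and isthmus, 0.31 for diencephalon and hypothalamus, 0.67 for hindbrain and spinal HOX genes and 0.32 for Cajal-Retzius cells. They were -0.02 for axon guidance, 0.14 for proliferation, -0.34 for pluripotency, -0.17 for astrocytes and the oligodendrocyte lineage, and 0.14 for stress, apoptosis and hypoxia. The endoderm, epithelium and muscle list had a median of -0.03 and a mean of -0.29 while its test pointed up, and the blood, endothelium and microglia list a median of 0.02, a mean of -0.08 and a test that pointed down (adjusted p = 0.88 for each). Genes higher in the embryonic hippocampus than in the other 3 tissues, a signature of 275 genes taken from the embryo arrays, rose in CHIR_8-16 by a median of 0.25 (0.29 and 0.25; 189 higher, 86 lower; adjusted p = 0.00025, 0.0026 with the block), 23 up and 3 down when adjusted over the list alone, and adjusted p = 0.82 with an estimated correlation. The ventral telencephalon signature fell, with a median of -0.14 (-0.15 and -0.10; adjusted p = 0.0083, 0.017 with the block), and adjusted p = 0.82 with an estimated correlation. The hippocampal signature lost its call without CHIR_8-16 replicate 2 (adjusted p = 0.056), and the ventral signature without WiBi_0-11 replicate 2 (0.13) and without CHIR_8-16 replicate 1 (0.099). The E15 cortex signature (155 genes, median 0.22), the genes at least 2-fold higher in hippocampus than cortex (1127 genes, 0.11) and those higher in cortex (919 genes, 0.14) did not pass. Nor did the E15 midbrain signature (746 genes), whose median was 0.06 while its mean was -0.04 and its test pointed down (adjusted p = 0.4). Across the 5 comparisons no call of a list or signature held with an estimated correlation. None of the 41 called medians changed sign under median scaling, quantile normalization, normexp with quantile normalization, or the deposited table, but 22 moved by over 1.5 times under at least 1 of these scalings. Between CHIR_8-16 and WiBi_0-11 medians over all 5 scalings ran from 0.37 to 0.63 for the WNT targets, from -0.99 to -0.42 for the mesenchyme list, from -0.36 to -0.23 for the pan-neuronal list, from 0.10 to 0.25 for the hippocampus signature and from -0.27 to -0.11 for the ventral signature. With dim values set to at least the lowest signal called well above background, a choice made after seeing the data, called medians moved by at most 0.17 and 1 of the 41 changed sign, the ventral telencephalon signature between CHIR_8-16 and CHIR_11-16.

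**Figure D1:**
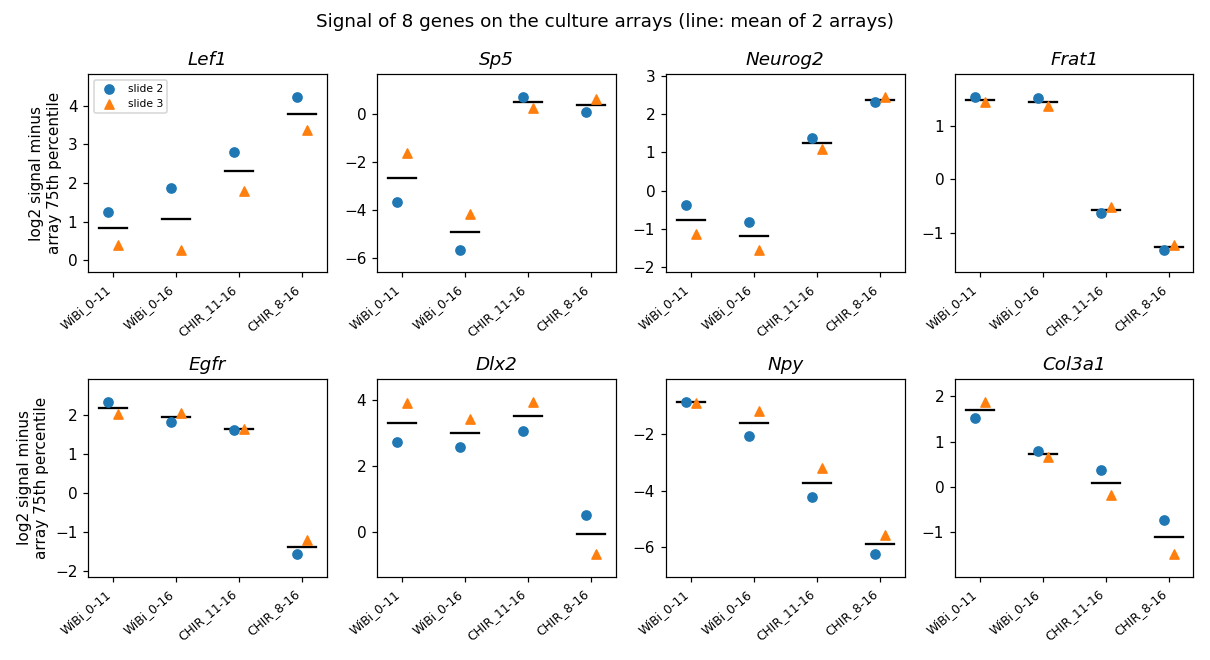
Log2 signal minus the 75th percentile of the array (y axis) for Lef1, Sp5, Neurog2, Frat1, Egfr, Dlx2, Npy and Col3a1 in the 4 culture groups (x axis), with circles for slide 2, triangles for slide 3 and a line at the mean of the 2 arrays. From WiBi_0-11 to CHIR_8-16, Lef1 and Neurog2 were 2.97 and 3.14 log2 units higher, and Egfr and Frat1 differed by -3.57 and -2.78.

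The comparison of CHIR_11-16 with WiBi_0-11 asked what the agonist did after the same inhibitor exposure. No gene passed by limma without a block (0 genes, smallest adjusted p = 0.102, 1200 genes with an unadjusted p under 0.05), and 3 genes, all 3 lower in CHIR_11-16, passed with slide as a block (3185 with an unadjusted p under 0.05). Without the block quantile normalization gave 3 genes and median scaling 2. With the block normexp with quantile normalization and the deposited table gave 0 genes each. A trended prior gave 1 blocked call, not among the 3, and quantile normalization alone gave 4 with the 3 among them. The blocked call with a gene symbol was Phf8-ps, a pseudogene at chr17:33202938-33202997, at least 2.96-fold higher in WiBi_0-11 (adjusted p = 0.009). The other 2, chosen after their values were seen, were transcripts without a symbol, probed at chr4:148120175-148120234 and chr10:67045387-67045446. Leaving out any of the 4 arrays compared took the blocked count to 0. The WNT targets Sp5 and Axin2 had log2 differences of 3.13 (SE 0.78) and 0.75, and Lef1 1.47 (SE 0.67). The other genes named in every comparison had log2 differences of -0.73 (Wnt8b), 0.75 (Prox1), 0.44 (Zbtb20), -0.32 (Emx2), -0.25 (Bcl11b), -0.39 (Tbr1), 0.16 (Fezf2), 0.19 (Dlx2), -0.48 (Reln) and 0.59 (Mki67), each with adjusted p = 1.

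By lists, 5 passed between CHIR_11-16 and WiBi_0-11 without the block and 7 with it. Proliferation genes were higher in CHIR_11-16 by a median log2 of 0.53 (0.65 on slide 2, 0.38 on slide 3), all 20 measured genes higher (adjusted p = 3e-10, 4.3e-07 with the block), and adjusted p = 0.6 with an estimated correlation. The WNT/beta-catenin targets were higher by 0.68 (0.88 and 0.59; 11 higher, 5 lower, 5 up when adjusted over the list alone; adjusted p = 0.00072, 0.0021 with the block), and adjusted p = 0.43 with an estimated correlation. The pallial progenitors were higher by 0.28 (0.18 and 0.21; 16 higher, 6 lower, 1 up when adjusted over the list alone; adjusted p = 0.00068, 0.0034 with the block), and adjusted p = 0.43 with an estimated correlation. The pan-neuronal list was lower, with a median of -0.26 (-0.35 and -0.17; 4 higher, 21 lower; adjusted p = 8e-04, 0.0011 with the block), and adjusted p = 0.5 with an estimated correlation. The midbrain and isthmus list was higher by 0.29 (0.68 on slide 2 and -0.01 on slide 3; 14 higher, 6 lower; adjusted p = 0.042, 0.066 with the block), and adjusted p = 0.87 with an estimated correlation. This last list turned its direction without WiBi_0-11 replicate 1 (adjusted p = 0.78) and did not pass without CHIR_11-16 replicate 2 (0.35), and the pan-neuronal list did not pass without WiBi_0-11 replicate 1 (0.24) or CHIR_11-16 replicate 2 (0.057). With the block the HOX list was also called (median 0.30, adjusted p = 0.021), as were Cajal-Retzius cells (-0.40, 0.02) and astrocytes and the oligodendrocyte lineage (-0.30, 0.014), all 3 lost with the block and an estimated correlation, under which 0 lists passed. Without 1 array the number of lists called ran from 3 without WiBi_0-11 replicate 1 to 9 without WiBi_0-11 replicate 2, and it was 8 without CHIR_11-16 replicate 1. When adjusted over the list alone, 0 members of the proliferation, pan-neuronal and midbrain lists passed. The hippocampal (-0.08) and isocortical (-0.03) lists did not pass (adjusted p = 0.87 for each).

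The embryonic hippocampus signature rose in CHIR_11-16 by a median of 0.17 (0.18 and 0.09; 173 higher, 102 lower; adjusted p = 0.00085, 0.0028 with the block), and adjusted p = 0.88 with an estimated correlation. The midbrain signature fell, with a median of -0.13 (-0.10 and -0.16; adjusted p = 0.011, 0.0057 with the block) and the genes higher in cortex than hippocampus fell, with a median of -0.09 (-0.13 and -0.09; adjusted p = 0.023, 0.012 with the block). For both, adjusted p = 0.88 with an estimated correlation, and both lost the call without WiBi_0-11 replicate 2 (0.13 each), the cortical genes also without CHIR_11-16 replicate 1 (0.2). With a 4-fold minimum for signature genes the test of these 2 signatures pointed up (adjusted p = 0.88 each). Without WiBi_0-11 replicate 2 the number of signatures called was 1. Over the 5 scalings the median ran from 0.06 to 0.19 for the hippocampus signature, from -0.13 to -0.06 for the midbrain signature, from -0.09 to -0.05 for the cortical genes and from 0.16 to 0.32 for the midbrain and isthmus list.

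The comparison of WiBi_0-16 with WiBi_0-11 asked what a longer inhibitor exposure changed. By limma 0 genes passed without a block (smallest adjusted p = 0.0881, 669 genes with an unadjusted p under 0.05) and 3, all 3 lower in WiBi_0-16, with slide as a block (2765 with an unadjusted p under 0.05). Quantile normalization without the block gave 3 genes. With the block normexp with quantile normalization and a trended prior gave 0 genes each. The deposited table gave 1 of the 3, and quantile normalization alone 4 with the 3 among them. Phf8-ps was the blocked call with a gene symbol, at least 2.18-fold higher in WiBi_0-11 (adjusted p = 0.011), beside the transcripts probed at chr4:148120175-148120234 and chr10:67045387-67045446. The blocked count was 1 without WiBi_0-16 replicate 2, a gene not among the 3, and 0 without any of the other 3 arrays compared. The WNT target Sp5 had a log2 difference of -2.25 (SE 0.78), Axin2 0.12 and Lef1 0.25. Differences of the other genes named in every comparison were -0.36 (Wnt8b), 0.14 (Prox1), 0.20 (Zbtb20), 0.06 (Emx2), -0.29 (Bcl11b), 0.10 (Tbr1), 0.17 (Fezf2), -0.32 (Dlx2), 0.06 (Reln) and -0.13 (Mki67), each with adjusted p = 1.

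By lists, 6 were called, all 6 lower in WiBi_0-16. The neural crest and mesenchyme list was lower, with a median of -0.76 (-0.75 on slide 2, -0.58 on slide 3; 2 higher, 16 lower; adjusted p = 1.7e-07, 1.8e-06 with the block), the WNT/beta-catenin targets with -0.53 (-0.43 and -0.40; 4 higher, 12 lower; 0.00087, 0.014) and the pallial progenitors with -0.24 (-0.38 and -0.06; 5 higher, 17 lower; 0.0042 in both fits). For each of these 3, adjusted p = 0.29 with an estimated correlation. Proliferation genes were lower, with a median of -0.32 (-0.49 and -0.16; 1 higher, 19 lower; adjusted p = 2.4e-05, 0.00058 with the block), the diencephalon and hypothalamus list with -0.49 (-0.44 and -0.45; 2 higher, 12 lower; 0.028, 0.043) and WNT ligands, receptors and modulators with -0.28 (-0.24 and -0.21; 5 higher, 17 lower; 0.043, 0.08). For each of these 3, adjusted p = 0.82 with an estimated correlation. When adjusted over the list alone, 1 member of the diencephalic list fell and 0 members of the other 5 lists changed. Calls were lost for the pallial list without WiBi_0-11 replicate 1 (0.17), for proliferation without WiBi_0-16 replicate 1 (0.37), for the diencephalic list without WiBi_0-11 replicate 2 (0.14) or WiBi_0-16 replicate 1 (0.36), and for the WNT ligand list without WiBi_0-11 replicate 2 (0.14), WiBi_0-16 replicate 1 (0.36) or WiBi_0-16 replicate 2 (0.054). The embryonic hippocampus signature fell, with a median of -0.13 (-0.15 and -0.08; adjusted p = 0.0017, 0.0053 with the block), genes higher in hippocampus than cortex fell, with a median of -0.16 (-0.19 and -0.12; 397 higher, 730 lower; 5.7e-05, 0.00033) and genes higher in cortex rose by 0.12 (0.09 and 0.16; 561 higher, 358 lower; 0.0044, 0.0038). For all 3 signatures, adjusted p = 0.6 with an estimated correlation, and the cortical genes lost the call without WiBi_0-11 replicate 1 (0.055) or WiBi_0-16 replicate 2 (0.19), and 5 signatures passed without WiBi_0-16 replicate 1. Over the 5 scalings medians ran from -0.62 to -0.23 for the WNT targets, from -0.58 to -0.18 for the diencephalic list, from -0.85 to -0.49 for the mesenchyme list, from -0.23 to -0.10 for the hippocampus signature, from -0.26 to -0.11 for genes higher in hippocampus and from 0.03 to 0.12 for those higher in cortex.

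The comparison of CHIR_8-16 with CHIR_11-16 asked whether the start of the agonist mattered. The groups also differed in the end of the inhibitors (day 8 against day 11) and the length of agonist exposure. The agonist dose of CHIR_11-16 is not stated, so these differences cannot be told apart from the start. By limma 0 genes passed without a block (smallest adjusted p = 0.0858, 975 genes with an unadjusted p under 0.05), 1 gene passed with quantile normalization, with median scaling or with a trended prior, and 2 passed with slide as a block, both lower in CHIR_8-16 (2971 with an unadjusted p under 0.05). The interneuron progenitor factor Sp8 fell 21.5-fold (log2 -4.43, SE 0.22, adjusted p = 0.035; -4.85 on slide 2 and -4.01 on slide 3; chr12:120090880-120090939), though another passing probe for it gave a log2 difference of -0.73. Ibsp was at least 9.79-fold higher in CHIR_11-16 (adjusted p = 0.035), and by another passing probe for it at least 4.14-fold. The blocked count was 4 without CHIR_8-16 replicate 1, with 0 of the 2 genes among them, and 0 without any of the other 3 arrays compared, and normexp with quantile normalization gave 34 blocked calls, 67.6% of them higher in CHIR_8-16. Median scaling gave a median log2 of all genes of -0.12 in this comparison and -0.08 in CHIR_8-16 minus WiBi_0-11, against 0.052 in the latter with the 75th percentile, and changes under it are relative to these shifts. Dlx2 had a log2 difference of -3.58, Wnt8b 2.50, Lef1 1.5, Reln 0.73, Tbr1 0.67, Emx2 0.59, Axin2 0.52, Fezf2 0.43, Zbtb20 -0.41, Mki67 -0.40, Prox1 -0.31, Bcl11b -0.22 and Sp5 -0.12, and none of these passed over all genes in either fit.

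By lists, 5 passed between CHIR_8-16 and CHIR_11-16. The Cajal-Retzius list was higher in CHIR_8-16 by a median of 0.70 (0.57 on slide 2, 0.96 on slide 3; 14 higher, 2 lower; adjusted p = 2.3e-07, 3.7e-05 with the block), and 4 members rose when adjusted over the list alone, among them Ebf2 and Zic1, transcription factors of these cells and of the dorsal midline. The ventral telencephalon and GABAergic list was lower, with a median of -1.22 (-0.13 and -1.87; 5 higher, 16 lower, 1 up and 9 down when adjusted over the list alone; adjusted p = 6.5e-07, 3.3e-05 with the block). The neural crest and mesenchyme list was lower, with a median of -0.46 (-0.89 and -0.45; 6 higher, 12 lower; adjusted p = 0.00011, 0.00088 with the block). For these 3 lists, adjusted p = 0.52 with an estimated correlation. Proliferation genes were lower, with a median of -0.37 (-0.23 and -0.56; all 20 lower; adjusted p = 6.6e-07, 3.3e-05 with the block), and adjusted p = 0.66 with an estimated correlation. The cortical hem, roof plate and choroid plexus list was higher by 0.27 (0.15 and 0.52; 16 higher, 1 lower; adjusted p = 0.0078, 0.034 with the block), and adjusted p = 0.63 with an estimated correlation. Without CHIR_8-16 replicate 2 neither the hem list (0.61) nor proliferation (0.14) passed, the hem list did not pass without CHIR_11-16 replicate 2 (0.061), and 9 lists passed without CHIR_8-16 replicate 1. When adjusted over the list alone, 0 members of the hem, proliferation and mesenchyme lists passed. The WNT targets had a median of 0.39 and a mean of -0.01 and did not pass (adjusted p = 0.41). The ventral telencephalon signature fell, with a median of -0.06 (mean -0.26; -0.05 and -0.15; 0.01 with dim values at their bound; adjusted p = 0.0077, 0.0098 with the block) and the genes higher in cortex than hippocampus had a median of 0.18 (0.21 and 0.13; 0.015, 0.0098). For both signatures, adjusted p = 0.74 with an estimated correlation, and both lost the call without 1 array: the first without CHIR_8-16 replicate 1 (0.093) or CHIR_11-16 replicate 2 (0.27), the second without CHIR_8-16 replicate 2 (0.16) or CHIR_11-16 replicate 1 (0.19). With a 4-fold minimum the test of the cortical genes pointed down (adjusted p = 0.017). The number of signatures called was 4 without CHIR_8-16 replicate 1 and 1 without each of the other 3 arrays. Over the 5 scalings medians ran from 0.02 to 0.18 for the genes higher in cortex, the lowest with median scaling, where the median of all genes was -0.12, and from -0.22 to -0.06 for the ventral signature, 0.11 to 0.27 for the hem list and -1.38 to -0.66 for the ventral list.

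The comparison of the 4 cultures given the agonist with the 4 given inhibitors alone asked what the agonist changed whatever its start. Without a block 2 genes passed, both lower with the agonist (3910 genes had an unadjusted p under 0.05). Agtr2, an angiotensin receptor, was at least 3.41-fold higher in the inhibitor cultures (n = 4 against 4, adjusted p = 0.033; chrX:21065564-21065623), and Frat1 fell 5.31-fold (log2 -2.41, SE 0.20, adjusted p = 0.033; -2.52 on slide 2 and -2.30 on slide 3). With slide as a block 820 genes passed, 477 higher and 343 lower, 225 of them by at least 2-fold, and 5745 genes had an unadjusted p under 0.05. The count without the block was 0 when any of the 8 arrays was left out, and with the block it was 3 without CHIR_8-16 replicate 2, 1 without CHIR_11-16 replicate 2, 1 without WiBi_0-16 replicate 1 and 0 without each of the other 5 arrays. Without the block normexp with quantile normalization gave 7 higher and 5 lower genes, and median scaling 11 higher and 4 lower.

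Genes with a symbol that passed with the block were named by their fitted difference. Sp5, a direct WNT target, rose 18.3-fold (log2 4.20, SE 0.69, adjusted p = 0.04; 5.06 on slide 2, 3.34 on slide 3; chr2:70315688-70315747). Foxb1, a factor of the diencephalon and caudal neural tube, was at least 9.11-fold higher with the agonist (adjusted p = 0.049), the dorsal neural tube factor Olig3 at least 15.1-fold (adjusted p = 0.033) and the WNT ligand Wnt10a at least 6.69-fold (adjusted p = 0.039; chr1:74850633-74850692). The lens crystallin genes Crybb1 and Cryge were at least 6.17-fold and 2.19-fold higher, the fatty acid binding protein gene Fabp4 at least 4.71-fold and the amylin gene Iapp at least 4.07-fold. Olig1 fell 14.4-fold (SE 0.65, adjusted p = 0.041). Npy fell (SE 0.62 log2, adjusted p = 0.044), with no exact fold since it was dim in CHIR_8-16. In the inhibitor cultures Gpr17 was at least 7.96-fold higher (adjusted p = 0.033), the matrix protein gene Mgp at least 5.53-fold and Lrrc17 at least 2.85-fold. Speer4a was 1.44-fold higher there, with 1 dim inhibitor array taken at its measured signal. Other passing probes gave log2 differences of 0.86 for Cntn2, 1.65 for Tnfrsf19, 1.42 for Nkd1, 3.01 for Lef1, 1.07 for Neurod1, -0.59 for Syn2 and, at the smallest, 0.64 for Nfib. Those for Crybb1, Myh3 and Prrx1 were at least 6.24-fold, 2.21-fold and 1.94-fold higher. Of the genes named in every comparison, Sp5 and Lef1 passed with the block. Others had log2 differences of 0.95 (Axin2), 0.71 (Wnt8b), 0.53 (Prox1), 0.13 (Zbtb20), -0.05 (Emx2), -0.21 (Bcl11b), -0.10 (Tbr1), 0.30 (Fezf2), -1.44 (Dlx2), -0.15 (Reln) and 0.45 (Mki67).

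By lists, 9 passed between agonist and inhibitor cultures, with medians from slide 2 and slide 3 in brackets. The WNT/beta-catenin targets rose by a median of 0.99 (1.08, 1.02; 12 higher, 4 lower; adjusted p = 3.9e-05, 0.00033 with the block; adjusted p = 0.22 with an estimated correlation), 8 of 16 adjusted over the list alone and 6 over all genes with the block, among them Sp5, Tnfrsf19 (4.61-fold), Lef1 (4.26-fold) and Nkd1 (3.86-fold). The pallial progenitors rose by 0.63 (0.54, 0.55; 18 higher, 4 lower; adjusted p = 2.3e-06, 2.5e-05 with the block; adjusted p = 0.2 with an estimated correlation), 8 of 22 adjusted over the list alone and 5 over all genes with the block, among them Neurog2 (6.85-fold), Dmrta1 (3.65-fold), Gli3 (2.39-fold) and Btg2 (1.62-fold). The pan-neuronal list fell, with a median of -0.31 (-0.26, -0.32; 3 higher, 22 lower; adjusted p = 4.5e-05, 5.8e-05 with the block; adjusted p = 0.2 with an estimated correlation), with 0 members adjusted over the list alone and the synaptic vesicle gene Syn2 (1.8-fold lower) over all genes with the block. These 3 lists also passed fry, which tests whether the genes move on balance (adjusted p = 0.018 each). Proliferation genes rose by 0.50 (0.78, 0.24; all 20 higher; adjusted p = 1.2e-07, 4.4e-06 with the block; adjusted p = 0.72 with an estimated correlation), 1 adjusted over the list alone, with Ccnb2, a mitotic cyclin, 1.69-fold higher. The diencephalon and hypothalamus list rose by 0.53 (0.37, 0.77; 9 higher, 5 lower; adjusted p = 0.019, 0.045 with the block), with Gbx2 at least 6.57-fold higher. The BMP pathway targets rose by 0.25 (0.34, 0.22; 13 higher, 2 lower; 0.041, 0.025). The stress, apoptosis and hypoxia list rose by 0.18 (0.07, 0.38; 15 higher, 5 lower; 0.022, 0.025), with Atf3 2.6-fold and Egr1 1.83-fold higher. The ventral telencephalon and GABAergic list fell, with a median of -0.50 (-0.13, -0.86; 6 higher, 15 lower; 0.032, 0.044), with somatostatin, Sst, 2.6-fold lower. For each of these 4 lists, adjusted p = 0.72 with an estimated correlation. The midbrain and isthmus list rose by 0.47 (0.66, 0.14; 15 higher, 5 lower; adjusted p = 0.02, 0.025 with the block), and adjusted p = 0.84 with an estimated correlation. Adjusted over the list alone, 4 diencephalic genes and 1 stress gene rose and 1 ventral gene fell, while 0 BMP targets and 0 midbrain genes passed.

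Calls of 5 of these 9 lists were lost when 1 array was left out. For the BMP targets adjusted p was 0.059 without WiBi_0-11 replicate 1, 0.11 without CHIR_8-16 replicate 2, 0.064 and 0.12 without CHIR_11-16 replicates 1 and 2, and 0.11 without WiBi_0-16 replicate 1. For midbrain and isthmus it was 0.14 without WiBi_0-11 replicate 1, 0.095 without CHIR_8-16 replicate 2, 0.071 without CHIR_11-16 replicate 2 and 0.099 without WiBi_0-16 replicate 1. For the ventral list it was 0.067 without WiBi_0-11 replicate 2, 0.35 without CHIR_8-16 replicate 2 and 0.057 without WiBi_0-16 replicate 2. For the diencephalic list it was 0.083 without CHIR_8-16 replicate 2 and 0.099 without WiBi_0-16 replicate 1, and for the stress list 0.084 without CHIR_8-16 replicate 2 and 0.12 without WiBi_0-16 replicate 2. The number of lists called was 4 without CHIR_8-16 replicate 2.

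The hippocampal list did not pass between agonist and inhibitor cultures, and its median of -0.15 and mean of 0.06 differed in sign while its test pointed down (adjusted p = 0.7). With the block its members Lef1, Fzd9, a WNT receptor (2.49-fold), and Neurod1, a neurogenic factor (1.99-fold), rose and Mpped1 fell 1.73-fold. The isocortical list (median 0.08, mean -0.01, adjusted p = 0.8) held 1 gene that passed with the block, Nfib, 1.79-fold higher. Axon guidance genes (median -0.03, mean 0.05, adjusted p = 0.8) went both ways: Robo3 rose 5.86-fold (SE 0.31, adjusted p = 0.033), Cntn2 4.84-fold and Epha3 1.49-fold, and Slit3 fell 1.5-fold. Of genes of the hindbrain and spinal cord, Hoxc4 was at least 2.83-fold higher, while the HOX list did not pass (median 0.38, adjusted p = 0.3). Hoxb4 was dim in CHIR_8-16 as well as in the inhibitor cultures, and was at least 2.2-fold higher in CHIR_11-16 than in WiBi_0-11. The Cajal-Retzius list had a median of -0.05, a mean of 0.29 and a test that pointed down (adjusted p = 0.89), and its members Calb2 and Lhx5 fell 2.12-fold and 2.02-fold. The glial genes S100b (6.71-fold) and Gja1 (2.88-fold) rose while Olig1 fell, and the neural crest genes Tfap2a (3.14-fold) and Prrx1 (2.25-fold) and the muscle gene Myh3 (at least 2.69-fold) rose, in lists that did not pass. Of those, the astrocyte and oligodendrocyte list had a median of -0.14, the mesenchyme list -0.12, and the endoderm, epithelium and muscle list a median of -0.08 against a mean of 0.23.

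The embryonic hippocampus signature rose with the agonist by a median of 0.21 (0.19 on slide 2, 0.23 on slide 3; 181 higher, 94 lower; adjusted p = 2.8e-06, 1.4e-05 with the block), with 41 genes up and 2 down when adjusted over the list alone and 32 up and 2 down over all genes with the block. Adjusted p = 0.67 with an estimated correlation. Its called genes included Wnt10a, Fabp4, the protease gene Adamts19 (at least 4.88-fold higher) and the G protein regulator Rgs13 (at least 2.11-fold higher). The signature does not stand for hippocampal neurons alone, and the hippocampal list did not pass. The other 5 signatures did not pass: hippocampus over cortex had a median of 0.11 (adjusted p = 0.067), cortex over hippocampus -0.07 (0.07), ventral telencephalon -0.14 (0.07), cortex 0.07 (0.67) and midbrain -0.07 (0.23). The signatures came from embryo arrays other than the arrays tested, and 30 of the 275 hippocampal signature genes were also in one of the gene lists. The number of signatures called was 4 without WiBi_0-11 replicate 1, 3 without CHIR_8-16 replicate 1, CHIR_8-16 replicate 2 or CHIR_11-16 replicate 2, and 2 without WiBi_0-11 replicate 2 or WiBi_0-16 replicate 1, and it was 3 after normexp with quantile normalization. Over the 5 scalings medians of the agonist comparison ran from 0.11 to 0.21 for the hippocampus signature, were at the smallest 0.63 for the WNT targets, and ran from 0.23 to 0.48 for the midbrain and isthmus list.

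Differences of CHIR_8-16 and CHIR_11-16 from the same WiBi_0-11 arrays had a correlation of 0.61 across genes, which are not independent replicates. Shared controls alone gave 0.502 in 20 simulations, with a covariance of 0.11 against 0.137 in the data. With slide as a block the simulated covariance was 0.0361, against the same 0.137 in the data. Both slides held all 4 groups, so a slide difference cancels from these differences. The spread without the block includes it (median residual SD 0.317, against 0.182 with the block), so 0.0361 is the nearer reference. The source of the covariance beyond that was not tested. No gene was called in both comparisons by limma without a block (0 higher, 0 lower, simulated 0 and 0.05). With the block 3 genes were lower in both, where the simulation gave 0. Independent calls would share 0.0069, a value that does not apply to comparisons with the same WiBi_0-11 arrays. The 3 were Phf8-ps and the transcripts probed at chr4:148120175-148120234 and chr10:67045387-67045446, above background in no culture group but WiBi_0-11. They also passed with the block for WiBi_0-16 against WiBi_0-11, so their overlap cannot be credited to the agonist. Each group had 2 arrays, so the WiBi_0-11 arrays were not divided between the comparisons.

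Correlation with the embryonic tissues asked which region each culture resembled more than the other cultures did. Values were centred on the same 8 cultures, so positive values in some groups force negative ones in others. The 4 group values are therefore not separate results. After centring each gene over the 8 cultures and over the 4 tissues, correlation across 24792 genes was highest with hippocampus for CHIR_11-16 (0.120 ± 0.006, SD, n = 2) and CHIR_8-16 (0.101 ± 0.004), against -0.084 ± 0.047 for WiBi_0-11 and -0.154 ± 0.006 for WiBi_0-16. Correlation with cortex was 0.060 ± 0.107 for CHIR_8-16, -0.014 ± 0.065 for CHIR_11-16, -0.102 ± 0.043 for WiBi_0-11 and 0.032 ± 0.042 for WiBi_0-16. With ventral telencephalon it was 0.119 ± 0.150 for WiBi_0-11, 0.096 ± 0.058 for WiBi_0-16, -0.009 ± 0.1 for CHIR_11-16 and -0.166 ± 0.073 for CHIR_8-16. With midbrain it was 0.073 ± 0.029, 0.029 ± 0.008, -0.077 ± 0.008 and -0.017 ± 0.139 in the same order. The hippocampal value minus the cortical value was 0.134 for CHIR_11-16 (0.176 on slide 2, 0.092 on slide 3), 0.041 for CHIR_8-16 (-0.038 and 0.119), 0.018 for WiBi_0-11 and -0.186 for WiBi_0-16. That of WiBi_0-11 was -0.016 without WiBi_0-16 replicate 2, -0.009 without WiBi_0-16 replicate 1, 0.011 without CHIR_8-16 replicate 1, 0.041 without CHIR_8-16 replicate 2, and 0.045 and 0.032 without CHIR_11-16 replicates 1 and 2. That of CHIR_8-16 was -0.022 without CHIR_8-16 replicate 2, 0.116 without CHIR_8-16 replicate 1, 0.064 without CHIR_11-16 replicate 1, 0.026 without WiBi_0-16 replicate 1, 0.013 without WiBi_0-16 replicate 2, and -0.006 by Spearman's method. Uncentred correlations ran from 0.935 to 0.957 and were highest with ventral telencephalon in each of the 4 groups, and the tissues correlated with one another at 0.952 to 0.98. With 2 arrays per group none of these differences between groups was tested.

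**Figure D2:**
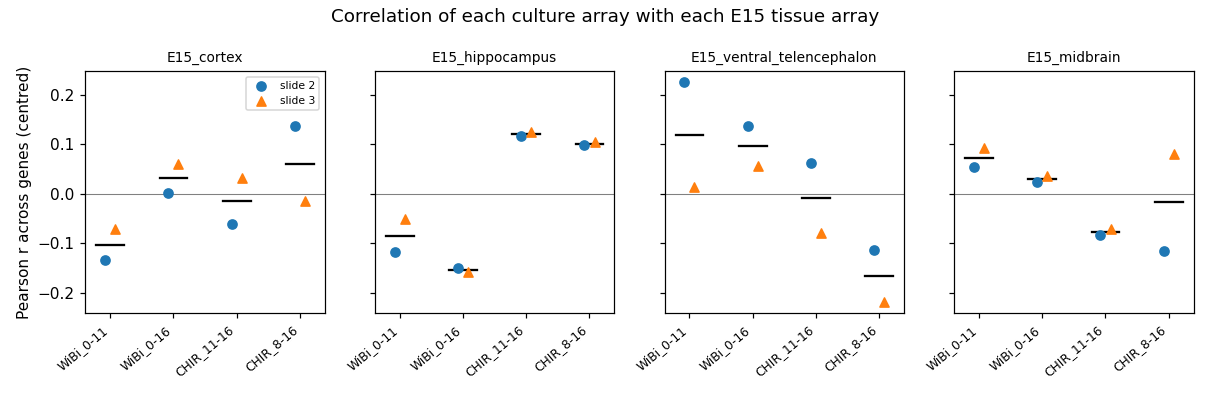
Centred Pearson correlation across genes (y axis) of each culture array with E15 cortex, hippocampus, ventral telencephalon and midbrain (4 panels), by culture group (x axis), with circles for slide 2 and triangles for slide 3. With hippocampus the mean was 0.101 for CHIR_8-16 and 0.120 for CHIR_11-16, above -0.084 for WiBi_0-11 and -0.154 for WiBi_0-16.

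In the embryonic tissues, 1127 genes were at least 2-fold higher in hippocampus than in cortex and 919 at least 2-fold higher in cortex, with 1 array each and no test. In hippocampus Synj1, low on the cortex array alone, was at least 404-fold higher, Ttr, transthyretin, 479-fold, Clic6 at least 163-fold, Wnt8b at least 151-fold and Wnt10a at least 60.3-fold. In cortex Agtrap was 501-fold and Ghrhr at least 3870-fold higher, both high on the cortex array alone. Pdzph1 was at least 17.8-fold and Klhl14 at least 4.12-fold higher, both lowest in hippocampus, with ventral telencephalon and midbrain above cortex. Sp5 was 67.7-fold, Prox1 14.6-fold, Lef1 5.63-fold, Zbtb20 5.38-fold, Emx2 3.79-fold, Reln 3.18-fold and Axin2 2.98-fold higher in hippocampus, and Tbr1 2.09-fold higher in cortex. Log2 differences were -0.54 for Bcl11b, -0.18 for Fezf2, -0.63 for Dlx2 and 0.30 for Mki67. The median log2 difference was 1.68 for the hippocampal list (13 of 22 genes at least 2-fold higher), 2.81 for the hem list (13 of 17), 1.57 for the WNT targets and 1.25 for Cajal-Retzius cells, each at percentile 100 of 10000 random lists of matched level, and 11 of 18 mesenchyme genes were at least 2-fold higher in hippocampus. It was -0.59 for the isocortical list (10 of 28 genes at least 2-fold higher in cortex, percentile 0). For the ventral list it was -0.18 (percentile 14.5) and for the pan-neuronal list -0.22 (percentile 8.2). Lists for mesenchyme, for endoderm, epithelium and muscle, for BMP targets, WNT ligands and pallial progenitors also lay at percentile 100. Of the endoderm, epithelium and muscle genes, 6 of 11 were at least 2-fold higher in hippocampus. Percentiles were 99.9 for proliferation and 99.3 for blood, endothelium and microglia. Across 24289 genes the hippocampus minus cortex difference of the embryo correlated at 0.011 with CHIR_8-16 minus WiBi_0-11 (-0.042 on slide 2, 0.068 on slide 3), 0.091 with CHIR_11-16 minus WiBi_0-11 (0.1, 0.048), -0.18 with WiBi_0-16 minus WiBi_0-11 (-0.13, -0.16), -0.068 with CHIR_8-16 minus CHIR_11-16 (-0.13, 0.039) and 0.14 with agonist minus no agonist (0.093, 0.15). After normexp with quantile normalization the counts were 544 and 291, and 493 genes were higher in cortex in the deposited table.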

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

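The tests of array scaling for the mesenchyme list, and of another list of mesenchymal genes, were chosen only after the mesenchyme result was seen.

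A sample far from the others was found in 2 of 36 groups of 4 cultures checked, and chance alone marks about 1 in 20 groups. Axin2 in CHIR_8-16 replicate 2 was 0.71, away from the other 3 agonist cultures. Wnt8b in WiBi_0-11 replicate 1 was -0.80, away from the other 3 cultures without the agonist.

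Differences between CHIR_8-16 and CHIR_11-16 were tested directly, since both groups received the agonist, though the end of the inhibitors differed between them as well. With slide as a block, the fitted log2 difference was -4.43 for Sp8, where another passing probe gave -0.73. It was -5.08 for Ibsp, which was not well above background in CHIR_8-16 and was at least 9.79-fold higher in CHIR_11-16 (at least 4.14-fold by another passing probe). By camera without the block the Cajal-Retzius list differed by a median of 0.70, the cortical hem, roof plate and choroid plexus list by 0.27, the ventral telencephalon and GABAergic list by -1.22, proliferation by -0.37, and neural crest and mesenchyme by -0.46. The embryonic ventral telencephalon signature differed by a median of -0.06 (0.01 with dim values set to at least the lowest signal called well above background) and the genes higher in cortex than hippocampus by 0.18 (0.02 with median scaling). None of these list and signature calls held with an estimated correlation.

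The count of genes between agonist and inhibitor cultures rested on the slide. Of the 35 splits of the 8 arrays into 4 and 4, 18 put 2 arrays of each slide on each side as the real one does, too few for a share under 0.05: the real split, 1 of the 18, called 2 genes without a block and 820 with slide as a block, and the highest other count was 0 in both fits. Other splits put 3 or 4 arrays of a slide on the same side: without a block the split that follows the slides called 6752 genes, which points to a structure of the samples by slide, and with the block the highest count of the 16 splits with 3 arrays of a slide on a side was 1. Scaling of the arrays is argued against as the source of the slide difference, since 7405 genes were still called between slides after quantile normalization against 8778 before; RNA batch, culture batch, labelling and hybridisation cannot be told apart, as all of them could follow the slide.

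The mesenchyme list was higher in WiBi_0-11 than in CHIR_8-16 and WiBi_0-16 by camera, though neither call held with an estimated correlation. Scaling of the arrays is argued against there, as the smallest median difference was 0.42 after quantile normalization or normexp with quantile normalization, though this was down from 0.85. For CHIR_11-16 the same test decided nothing, because its median difference was 0.15 before any rescaling; the scaling test was first posed for all 3 groups together and was divided after this value was seen. A larger share of mesenchymal cells in WiBi_0-11 may be a source: in WiBi_0-11 the abundant collagen genes Col1a1, Col1a2 and Col3a1 were at 1.74 ± 0.11, 2.22 ± 0.14 and 1.70 ± 0.26 (SD, n = 2), against -1.02 ± 1.36, 0.35 ± 1.19 and -1.10 ± 0.52 in CHIR_8-16, while Dcn was at -0.48 ± 0.21 against -0.82 ± 1.16. That source stays open, since another list of 20 mesenchymal genes, 19 of them measured and none in the first list, was higher in WiBi_0-11 by medians of 0.29, 0.25 and 0.64 against CHIR_8-16, CHIR_11-16 and WiBi_0-16, where 0.3 in each was needed and 0 or less in any would have excluded it. No other gene list holds genes of the first list, 11 of whose 18 measured genes were at least 2-fold higher in embryonic hippocampus than cortex, and a direct effect of the treatments on these genes was not tested.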

How the results depend on the processing

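The alternatives with the replicate block beyond the block itself were chosen after seeing the data. Of the counts and main values, 148 stayed within their limits under the alternatives and 116 moved. Of the values for genes, lists and directions, 3197 were labelled unchanged, 185 became stronger, 168 weaker, 121 counts by direction moved and 5 reversed. The unchanged label includes counts by direction. For values called under neither setting it does not show that direction was kept. The cause was not tested for any change, except that leave-one-out leaves fewer arrays and a 4-fold minimum fewer genes. Dim signal limits some folds to lower bounds, with 59.06% to 71.18% of the non-control spots of an array well above background.

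For CHIR_8-16 minus WiBi_0-11 (3 genes) quantile normalization gave 11, median scaling 5, and no filter on dim probes, the mean of all passing probes and only the 2 groups compared 0 each, and leave-one-out 0 to 0. The replicate block gave 79 genes; with the replicate block normexp and quantile gave 444, series values 195, a trended prior 1030 and leave-one-out 0 to 110. For CHIR_11-16 minus WiBi_0-11 (0 genes) quantile normalization gave 3, median scaling 2 and the replicate block 3. For WiBi_0-16 minus WiBi_0-11 (0 genes) quantile normalization gave 3 and the replicate block 3. For CHIR_8-16 minus CHIR_11-16 (0 genes) quantile normalization, median scaling and a trended prior gave 1 each and the replicate block 2.

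For agonist minus no agonist (2 genes) normexp and quantile gave 12, quantile normalization 0, median scaling 15, no filter on dim probes 0, well above background on all 8 culture arrays 1, a trended prior 530, the average contrast in the 4-group fit 1 and leave-one-out 0 to 0. The replicate block gave 820; with the replicate block a minimum of 2-fold gave 225, normexp and quantile 1248, series values 544, a trended prior 2179, the average contrast 1265 and leave-one-out 0 to 3. The calls shared by CHIR_8-16 and CHIR_11-16 against WiBi_0-11 that were lower numbered 3 with the replicate block against 0 without.

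Gene lists called numbered 5 (CHIR_8-16 minus WiBi_0-11), 5 (CHIR_11-16 minus WiBi_0-11), 6 (WiBi_0-16 minus WiBi_0-11), 5 (CHIR_8-16 minus CHIR_11-16) and 9 (agonist). With an estimated correlation the count was 0 in each of the 5 comparisons, with or without the replicate block, and with fry 0, 0, 0, 0 and 3. Leave-one-out gave 5 to 12, 3 to 9, 4 to 7, 4 to 9 and 4 to 10 lists. The list for midbrain and isthmus, CHIR_11-16 minus WiBi_0-11, had adjusted p from 3.8e-06 to 0.78 over leave-one-out, reversed at 0.78 without WiBi_0-11 replicate 1.

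Signatures called numbered 2, 3, 3, 2 and 1 in the same order. With an estimated correlation the count was 0 in each of the 5 comparisons, with or without the replicate block. A 4-fold minimum gave 1 in each of the first 4 comparisons, and normexp and quantile gave 3 in the agonist comparison. Leave-one-out gave 2 to 2, 1 to 4, 2 to 5, 1 to 4 and 1 to 4. With the 4-fold minimum the E15 midbrain signature and cortex over hippocampus reversed in CHIR_11-16 minus WiBi_0-11 (adjusted p = 0.88 and 0.88), and cortex over hippocampus in CHIR_8-16 minus CHIR_11-16 (0.017). The E15 ventral telencephalon signature in WiBi_0-16 minus WiBi_0-11 had adjusted p from 0.0071 to 0.16 over leave-one-out and reversed without WiBi_0-16 replicate 2 (0.039).

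The hippocampus minus cortex correlation of WiBi_0-11 (0.018) was 0.024 by Spearman's method, 0.022 with genes well above background on all 12 arrays and -0.016 to 0.045 over leave-one-out. It was 0.107 to 0.195 for CHIR_11-16 (0.134) and -0.246 to -0.169 for WiBi_0-16 (-0.186) over leave-one-out. Embryonic genes at least 2-fold higher in hippocampus than cortex (1127) numbered 544 with normexp and quantile, and those higher in cortex (919) 291 with normexp and quantile and 493 in the series table.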

Other observations

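The tests against WiBi_0-16 were chosen only after the data were seen, and the tests of the transcripts high in WiBi_0-11 were set before their results.

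Against the cultures held in inhibitors until day 16, the WNT/beta-catenin targets were higher in both agonist groups, by a median log2 of 1.43 in CHIR_8-16 (adjusted p = 4.7e-07, camera without a block) and 1.05 in CHIR_11-16 (adjusted p = 2.1e-07). The pallial progenitors were higher by 0.81 and 0.53, proliferation genes by 0.45 and 0.82, the diencephalon and hypothalamus list by 0.48 and 0.66, the midbrain and isthmus list by 0.24 and 0.69 and the stress list by 0.22 and 0.37, in that order, and the pan-neuronal list was lower, with -0.26 and -0.38. The ventral telencephalon and GABAergic list was lower in CHIR_8-16 (-1.02, adjusted p = 0.00016). In CHIR_11-16 the BMP targets (0.37), the WNT ligands (0.18), the mesenchyme list (0.27) and the endoderm, epithelium and muscle list (0.51) were higher as well. The embryonic hippocampus signature was higher by 0.30 in CHIR_8-16 (adjusted p = 5e-08) and 0.24 in CHIR_11-16 (adjusted p = 9.7e-07), and genes higher in hippocampus than cortex by 0.21 and 0.14. The ventral telencephalon signature was lower in CHIR_8-16 (-0.19) and the genes higher in cortex than hippocampus were lower in CHIR_11-16 (-0.24). With slide as a block the midbrain and isthmus list did not pass in CHIR_8-16 (adjusted p = 0.067, against 0.02 without) nor the WNT ligands in CHIR_11-16 (0.064, against 0.023), the BMP targets passed in CHIR_8-16 as well (median 0.39, 0.031), and the other calls held. With an estimated correlation 0 of these 11 calls for CHIR_8-16 and 0 of the 14 for CHIR_11-16 held, the smallest adjusted p being 0.14 and 0.2. By limma 0 single genes passed in either comparison, without or with the slide block, while 2525 and 1983 genes had an unadjusted p under 0.05 without the block and 5569 and 4936 with it.

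Among members that passed only when adjusted over the list alone, named after their values were seen, the interneuron factors Dlx1 (log2 -3.45) and Gsx2 (-2.98) were lower in CHIR_8-16 than in WiBi_0-11, as were the matrix genes Postn (-3.10) and Col1a1 (-2.77). The dorsal midline factor Zic1 (2.79) and the axon genes Robo3 (2.88) and Cntn2 (2.64) were higher, though other passing probes gave 1.46 for Zic1 and 1.11 for Cntn2. In CHIR_11-16 the WNT targets Tcf7 (at least 2.98-fold), Tnfrsf19 (log2 1.62), Nkd1 (1.37) and Ccnd1 (1.11) were higher than in WiBi_0-11, and Npy was lower (-2.85), though another passing probe gave 0.04 for Nkd1 and one for Tnfrsf19 a smaller rise.

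By measured signal, genes 4-fold or more above every culture array outside their group on both arrays numbered 5 in WiBi_0-11, 4 in CHIR_8-16, 0 in CHIR_11-16 and 2 in WiBi_0-16, and genes as far below them 0, 7, 0 and 1; with dim values of the lower side at no less than the lowest signal called well above background, a choice made after seeing the data, these became 1, 2, 0 and 1 above and 0, 6, 0 and 1 below. The 5 in WiBi_0-11 were the receptor gene Il23r, the pseudogene Phf8-ps, the olfactory receptor gene Olfr1179 and the transcripts probed at chr4:148120175-148120234 and chr10:67045387-67045446, none well above background in any other culture. Their means were thus at least 5.67-fold, 2.4-fold, 4.4-fold, 7.3-fold and 9.15-fold higher, in that order, and the 4-fold gap to each array held for the chr10 transcript only. A sequence that the 5 probes share could have given them the same signal, but the longest stretch that a pair of them shares was 7 nt, at or below the median of 8 nt in 200 random sets, which argues against it. Transcription of the annotated genes stays open: the other 2 probes of these genes, both for the chr4 transcript and neither above background, differed by a median of 0.19 log2 units.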
